A study of Homo sapiens with 8 samples.

How the data were processed

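H3K27me3 chromatin immunoprecipitation and sequencing was run on MOLM14 cells treated with DMSO or AC220 for 24 h, with Drosophila S2 cells added before lysis, per the labels. Cells were fixed in paraformaldehyde and sonicated, per the labels' protocols. Of the 8 samples, 4 are immunoprecipitated libraries (DMSO 1, DMSO 2, AC220 1 and AC220 2) and 4 are inputs, whose values were not used here. Treatment and number were taken from the sample titles. Nothing in the labels says that the libraries of one treatment came from separate cultures. Every exact p-value therefore measures the spread between these libraries, which may be technical. The permutation p-values of the correlations measure agreement across chromosomes or bands, and not that spread.

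BWA 0.7.10-r789 and MACS2 2.1 are named in the submitters' processing notes, without roles or settings. Each immunoprecipitated library has 1 deposited list of broad peaks, so peaks were called per library and not on pooled samples. Columns give peak positions in bp, and their order is that of the broad peak format. The fold enrichment deposited for each peak is a ratio over the background of its own library. The deposited lists give a p-value and a q-value for each peak as -log10, each a value of the authors for that peak within its library. The deposited score equalled 10 times the -log10 q, rounded down, in at least 99.99% of peaks of every library. The smallest -log10 q was 1 to the nearest whole number, so peaks with a q of up to about 0.1 were listed. Whether inputs or Drosophila reads entered the peak calls is not given in the sources used here. The lists hold no read counts: depth per library is unknown, no interval or detection floor that needs it is given, and in the report q was used only to rank or filter peaks within a list. The closing section alone sets values of different lists side by side: a background level derived from the fold and p of each list's repeated shortest peaks, and the fold of those peaks in AC220 2 as a minimum for DMSO 2 peaks.

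The genome build is not given in the sources used here. Contig names and peak ends matched GRCh37 (hg19): the highest peak end on chromosome 1 was 249236554, within the GRCh37 length of 249250621. Chromosome lengths, bands and Giemsa stains of hg19 came from the table shipped with circlize 0.4.16 in R 4.3.3. Positions are printed counting from 1. The gene table at hand is on GRCh38.p14, a different build, and coordinates were not converted. The planned results on promoters, gene lists, named genes and annotation classes were therefore not run, and gene names are given as textbook background for a band. Bands of the HOX clusters, MEIS1, CEBPA, CEBPE, SPI1, ITGAM, CD14, CSF1R, EZH2, CDKN2A and MYC, a list fixed before the data were examined, stood in for those genes, and the band of FLT3 was added; this use of bands was chosen afterwards.

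Totals were taken over chromosomes 1 to 22, X and Y; windows, bands and chromosome values over chromosomes 1 to 22 and X. Peak number, covered length, median width and broad peaks (at least 10 kb) were computed per library with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. Groups were compared on log2 values by an exact permutation test, two-sided, over the 6 assignments of the 4 libraries. Overlap was measured with bedtools 2.31.1 as the Jaccard index in bp for the 6 pairs of libraries, and a peak counted as shared when at least 50% of its length lay in peaks of the other list. The covered share of a window is the percentage of its bases inside any deposited peak of a library. The log2 ratio of darkest to unstained coverage per library was compared by the same exact test, added after the data had been seen. Windows of 5 kb were called by the separation rule of 25 percentage points, applied also to the other splits of the libraries into pairs. Adjacent called windows were joined, and the 5 longest regions in each direction are named, a rule fixed before the data were examined; the order among regions of equal length, by mean separation, was set afterwards. Band, stain and correlation analyses were likewise chosen after the data had been seen. Bands of at least 1 Mb with at least 2% covered in both DMSO libraries were compared, and the 5 bands in each direction are named, ranked by whichever set differed less. The widest and strongest peaks of each list were also chosen for naming after the data had been seen. Correlations (scipy 1.17.1) used 100000 permutations and Benjamini-Hochberg adjustment over 4 coefficients. Figures were drawn with matplotlib 3.10.9.

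The window rule was run on simulated peak lists of 10000 windows with widths drawn from the real libraries. In them 200 of 200 planted lower and 200 of 200 planted higher windows were recovered, and 430 other windows were called. Planted windows were covered over most of their length under a treatment and cleared of peaks under the other, so their recovery was built in. Widths were drawn separately for each library, so the 430 do not give the error of the rule in the real lists. Alternatives fixed before the data were examined were a -log10 q of at least 2, peaks of at least 1 kb, equal covered length in all lists (strongest peaks kept), peaks under 3 kb apart joined, a separation of 50 points, windows of 10 kb and 2 kb, overlap of 1 bp, all sequences, leaving out each library, and comparison within replicate numbers. Leaving out centromeric, heterochromatic and stalk bands, trimming each DMSO list to the length of its AC220 list, and all settings tried on chromosomes, bands and stain classes were added after the data had been seen. Trimming the DMSO lists removes DMSO coverage alone, so it cannot lower a ratio of AC220 to DMSO.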

Results

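MOLM14 is an established human acute myeloid leukaemia cell line that carries an internal tandem duplication of FLT3, a receptor tyrosine kinase of blood progenitors. Quizartinib (AC220) inhibits that kinase. Cells were treated with AC220 or with its solvent DMSO for 24 h, and H3K27me3, the repressive histone mark written by the Polycomb complex PRC2, was mapped by chromatin immunoprecipitation and sequencing. The question was whether FLT3 inhibition altered this mark. The series holds 8 samples: 2 immunoprecipitated libraries of each treatment, analysed here through 1 deposited peak list each, and 4 input samples, for which no values were used here. Drosophila cells had been added before lysis as a reference, but the lists give positions and within-library scores, so the amount of mark per cell was not measured here and read depth is unknown. DMSO 1 held 104980 peaks on the 24 main chromosomes, DMSO 2 held 117556, AC220 1 held 104566 and AC220 2 held 139642. The libraries numbered 1 are called set 1 and those numbered 2 are called set 2, because the lists of set 2 covered about 2.5 times the length of set 1 under both treatments (2.55-fold for DMSO and 2.59-fold for AC220). This gap in covered length between sets exceeds that between treatments, so values within each set are given beside pooled ones.

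H3K27me3 peaks covered less of the genome with AC220 in both sets. In set 1 the covered length was 232 Mb with DMSO and 192 Mb with AC220, which is 17.2% lower, and in set 2 it was 591 Mb and 497 Mb, which is 15.9% lower. The lower coverage went with narrower peaks: the median peak width was 1211 bp with DMSO and 996 bp with AC220 in set 1, and 2321 bp and 1612 bp in set 2. A domain can be called as several peaks, so peak width is not domain width. Broad peaks of at least 10 kb, the form that H3K27me3 takes over silenced developmental loci, numbered 2656 and 1730 in set 1, and 14652 and 10683 in set 2. They held 17.9% of the covered length in DMSO 1 against 13.8% in AC220 1, and 52.6% in DMSO 2 against 41.2% in AC220 2. The number of peaks had no common direction, being 0.394% lower with AC220 in set 1 and 18.8% higher in set 2.

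Pooled over sets, covered length was 411 ± 254 Mb (SD, n = 2) with DMSO and 344 ± 215 Mb (SD, n = 2) with AC220, a log2 ratio of -0.26 (exact permutation test, two-sided, p = 0.667). The median width was 1766 ± 785 bp and 1304 ± 436 bp (exact permutation p = 0.667), the share in broad peaks 35.2% ± 24.5 and 27.5% ± 19.4 (exact permutation p = 0.667), and the number of peaks 111268 ± 8893 and 122104 ± 24802 (exact permutation p = 1; SD, n = 2 throughout). On the log2 scale the differences in covered length, median width and the share in broad peaks were smaller than the SD of either treatment, and the difference in peak number lay between the SDs of the treatments; with 2 libraries against 2, this exact test cannot give a two-sided p below 0.33. The pooled direction depended on single libraries: covered length came out higher with AC220 without DMSO 2 (log2 ratio 0.41) or without AC220 1 (0.42), since either removal leaves the sets unbalanced.

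**Figure D1:**
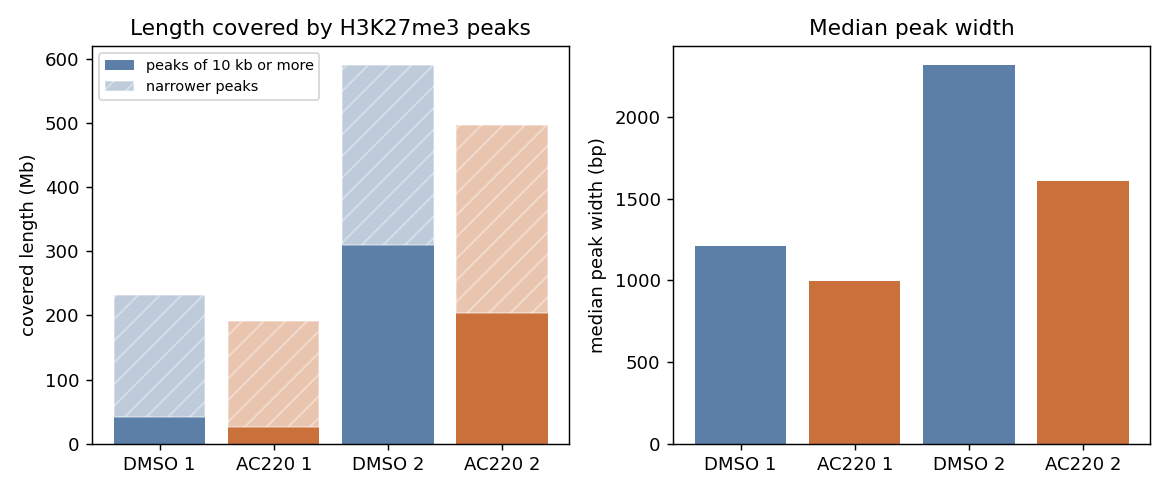
Left, length in Mb covered by H3K27me3 peaks in each library (bars), with peaks of at least 10 kb solid and narrower peaks hatched; right, median peak width in bp. Blue is DMSO and orange is AC220; within each set the AC220 bar is lower, 192 against 232 Mb in set 1 and 497 against 591 Mb in set 2.

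A shared core of domains lay under both treatments. In all, 127 Mb were covered in all 4 libraries, 19% of the 668 Mb covered in any. Bases covered in both DMSO libraries and in neither AC220 library came to 11.8 Mb, and bases covered in both AC220 libraries and in neither DMSO library to 3.48 Mb. The crossed pairs of libraries, which share neither treatment nor number, alone covered 4.70 Mb (DMSO 1 with AC220 2) and 5.69 Mb (DMSO 2 with AC220 1). Set 2 alone covered 173 Mb and set 1 alone 0.351 Mb. The Jaccard index, the shared length divided by the joint length, was 0.366 between the DMSO libraries and 0.356 between the AC220 libraries. It was 0.444 between DMSO 1 and AC220 1 and 0.651 between DMSO 2 and AC220 2, and averaged 0.359 for the crossed pairs. Lists of unequal length cannot reach a high index, which bears on every pair from different sets. With all lists trimmed to equal length the mean index was 0.524 within sets, 0.418 within treatments and 0.411 for crossed pairs. Most peaks of set 1 lay in the longer lists of set 2 whatever the treatment: of DMSO 1 peaks, 89.7% had at least 50% of their length inside DMSO 2 peaks and 84.1% inside AC220 2 peaks, and of AC220 1 peaks 88.2% lay likewise inside AC220 2 peaks and 91.2% inside DMSO 2 peaks.

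The widest domains were present under both treatments. Some of those of DMSO 2 were covered less in AC220 1 than in DMSO 1, and some of those of AC220 2 were covered more. Choosing the widest peaks of a list can favour the treatment of that list. The widest peak of DMSO 1 (chromosome 10, 102466461 to 102555219, GRCh37, 88.8 kb), of DMSO 2 (102324577 to 102595452, 271 kb) and of AC220 2 (102324485 to 102595371, 271 kb) lay in band 10q24.31, and AC220 1 had its second widest peak there (102466733 to 102555795, 89.1 kb). The DMSO 2 domain was covered over 90.6% of its length in DMSO 1, 91.5% in AC220 1 and 99.97% in AC220 2. In 12q13.13, the band of the HOXC cluster of body-patterning transcription factors, a peak of 255 kb in DMSO 2 (chromosome 12, 54125090 to 54379941) was covered over 97.7% in AC220 2. Over the same interval DMSO 1 was covered over 87.2% and AC220 1 over 85.8%. In 2q31.1, the band of the HOXD cluster, the fourth widest DMSO 1 peak (chromosome 2, 176933448 to 177004404, 71.0 kb) was covered over 95.5% in AC220 1, 100% in DMSO 2 and 98.3% in AC220 2. Among the other DMSO 2 domains, one of 269 kb in 10q26.11 (chromosome 10, 119239268 to 119508152) was covered over 84.8% in DMSO 1, 71.2% in AC220 1 and 97.2% in AC220 2. One of 262 kb in 6q23.2 (chromosome 6, 131983223 to 132245428) was covered over 86.0%, 71.1% and 96.4% in the same order. The widest AC220 1 peak lay in 6p21.33 (chromosome 6, 30350462 to 30451348, 101 kb) and was covered over 97.2% in DMSO 1. Among the widest AC220 2 peaks, that in 5q31.1 was covered over 61.7% in DMSO 1 and 69.35% in AC220 1. That in 1q32.1 was covered over 87.2% and 93.9%. The AC220 2 peak in 14q32.2 went the other way, at 80.6% and 78.3%. Gene names here are those of textbook band maps; the genes inside each interval were not determined, because no annotation of this build was used here.

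**Figure D2:**
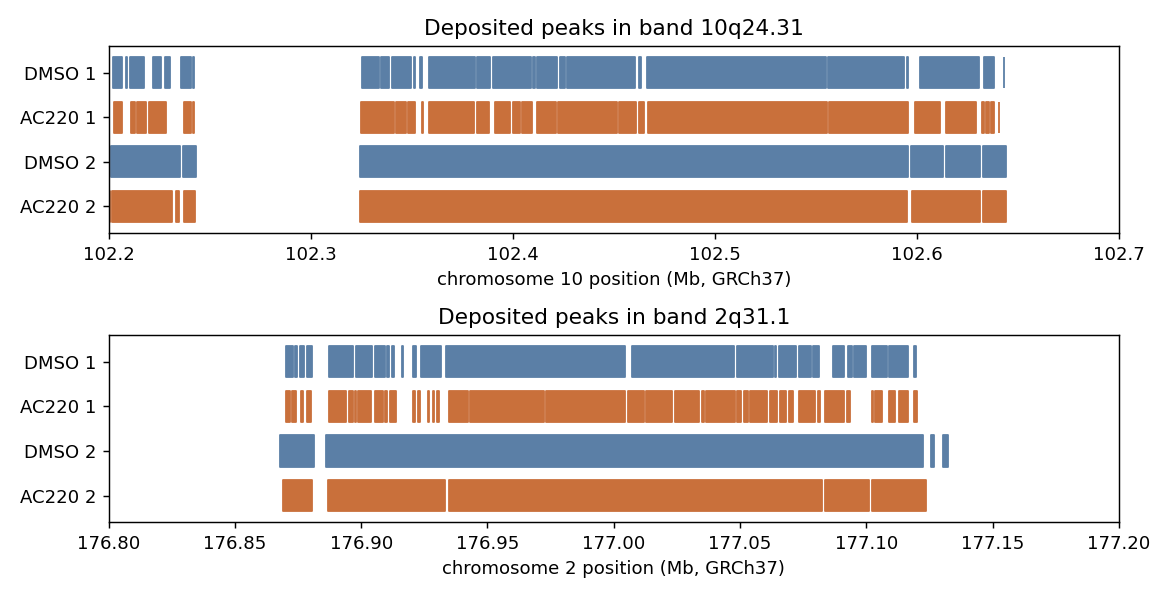
Deposited H3K27me3 peaks (filled boxes) of the 4 libraries along part of band 10q24.31 on chromosome 10 and of band 2q31.1 on chromosome 2, in Mb of GRCh37. Blue is DMSO and orange is AC220; the domain of 271 kb on chromosome 10 is present as 1 peak in DMSO 2 and AC220 2 and broken into several peaks in the libraries of set 1.

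The lower coverage with AC220 was spread over the chromosomes and was unequal between them. In set 1 all 23 chromosomes examined (the 22 autosomes and X) had a lower covered share with AC220, and in set 2 it was lower on 22 of 23, chromosome 22 being the exception with a log2 ratio of 0.05. Among the autosomes with larger differences were chromosome 13 (log2 ratio -0.45 in set 1 and -0.39 in set 2), chromosome 4 (-0.35 and -0.45), chromosome 8 (-0.44 and -0.29) and chromosome 6 (-0.43 and -0.30). Chromosomes 17 (-0.06 and -0.03), 19 (-0.14 and -0.01) and 22 (-0.05 and 0.05) differed least by the mean of both sets. Chromosome 10 had the highest covered share in every library, with 14.2% and 29.2% in DMSO 1 and DMSO 2 against 11.5% and 25.3% in AC220 1 and AC220 2. Chromosome X had the lowest, at 0.433% and 2.47% against 0.319% and 1.44%. The log2 ratios of the sets were correlated across chromosomes, with Pearson's r = 0.79 (permutation p = 1e-05, n = 23) and Spearman's rho = 0.83 (permutation p = 1e-05). Without the 2 chromosomes farthest from the median of set 1, r was 0.76 and rho 0.78. Across 599 bands r was 0.73 and rho 0.76 (permutation p = 1e-05 for each). All 4 coefficients had a Benjamini-Hochberg adjusted p of 1e-05, the smallest that 100000 permutations can give. Chromosomes and bands of one library are not independent replicates. Across 5 kb windows, the DMSO minus AC220 differences in covered share of the sets had a correlation of only 0.087, so the agreement held for large units and hardly for single windows. Each chromosome taken alone gave an exact permutation p of 0.667 or 1. When each DMSO list was trimmed to the length of its AC220 list, the strongest peaks being kept, 5 chromosomes (6, 8, 10, 12 and 13) were lower with AC220 in both sets and 11 were higher, so the direction for most chromosomes followed the total.

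**Figure D3:**
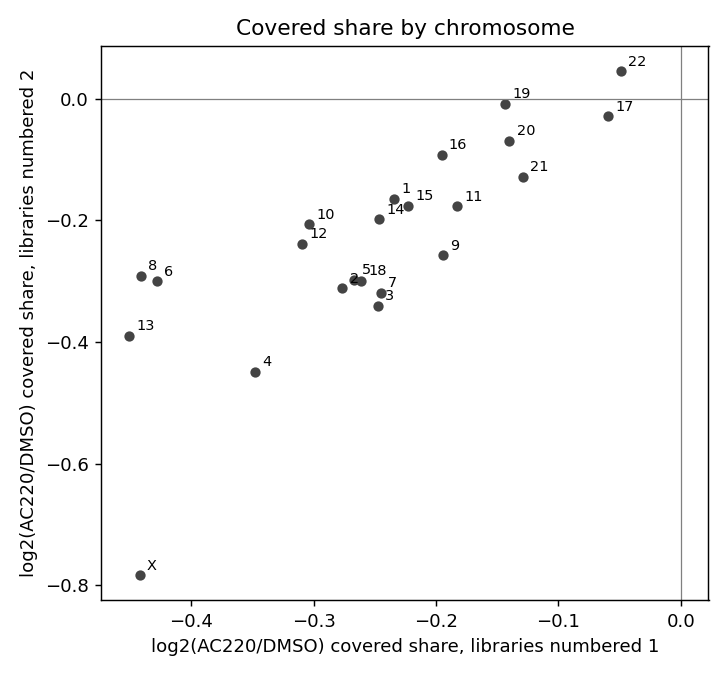
Each point is a chromosome, placed by the log2 ratio of AC220 to DMSO covered share in the libraries numbered 1 (x axis) and 2 (y axis); grey lines mark equal coverage. All points lie left of the vertical line and chromosome 22 alone lies above the horizontal one; with DMSO lists trimmed to AC220 lengths, 11 chromosomes were higher and 5 lower in both sets.

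Among unstained and grey Giemsa bands, coverage differed most, as a ratio, in the darkest class, the AT-rich and gene-poor part of the genome. There the covered share was 2.98% in DMSO 1 and 2.05% in AC220 1, which is 31.2% lower, and 12% in DMSO 2 and 7.93% in AC220 2, which is 34.0% lower. In unstained bands, which are rich in genes, it was 9.99% and 8.61% in set 1 (13.8% lower) and 23.1% and 20.6% in set 2 (10.7% lower). By ratio, the intermediate classes were ordered by stain except the lightest grey class, which was 12.5% and 9.08% lower. The next was 21.1% and 16.8% lower and the dark grey class 23.8% and 25.6% lower. In percentage points the darkest class did not differ most. In set 1 it differed by less than unstained bands, and in set 2 by less than the dark grey class (17.85% in DMSO 2 and 13.28% in AC220 2). The variable heterochromatic bands, of which little was covered (1.14% in DMSO 1 and 2.45% in DMSO 2), were 34.5% and 23.1% lower, in set 1 more than the darkest class, and centromeric bands were 22.5% and 19.5% lower. Of 599 bands of at least 1 Mb with at least 2% covered in both DMSO libraries, 458 were lower with AC220 in both sets, 58 were higher in both and 83 went in opposite directions. All 41 of the darkest bands and 62 of 65 dark grey bands were lower in both sets, against 225 of 324 unstained bands, of which 43 were higher. The filter set a minimum for DMSO and none for AC220, which can favour lower values with AC220 in sparsely covered bands. The darkest class, at 2.98% in DMSO 1, lay near that minimum. The log2 ratio of the darkest bands differed from that of unstained bands by -0.33 in set 1 and -0.44 in set 2, and by -0.19 and -0.26 with each DMSO list trimmed to its AC220 length. With that trimming the unstained bands were slightly higher with AC220 (0.03 and 0.05) and the darkest still lower (-0.15 and -0.21). The darkest class also differed most between the sets of the same treatment. Its covered share in set 2 was 4.03 times that in set 1 with DMSO and 3.87 times with AC220. In unstained bands these ratios were 2.31 and 2.39. Per library, the log2 ratio of darkest to unstained coverage was -1.34 ± 0.57 with DMSO and -1.72 ± 0.49 with AC220 (SD, n = 2; exact permutation test, two-sided, p = 0.667), a difference within the spread between libraries, and bands were examined after the data had been seen.

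**Figure D4:**
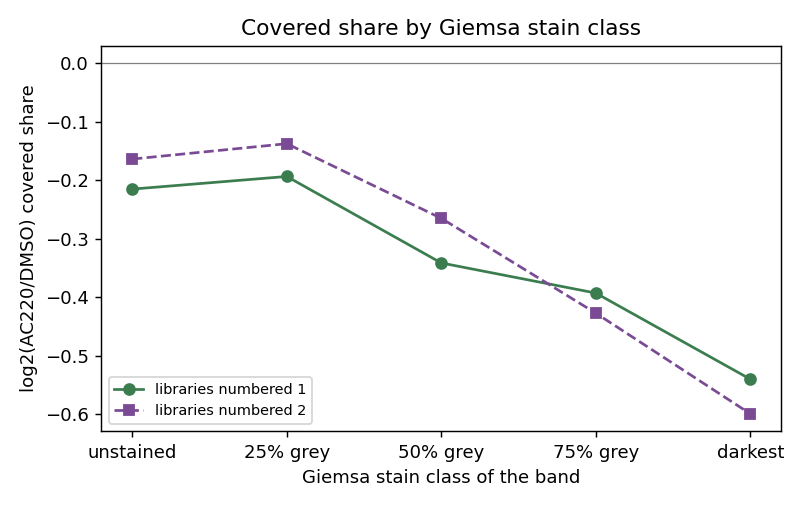
Log2 ratio of AC220 to DMSO covered share (y axis) in each Giemsa stain class from unstained to darkest (x axis), for the libraries numbered 1 (circles) and 2 (squares); each point is 1 ratio with no error. Both lines are lowest in the darkest bands, at -0.54 and -0.60; with DMSO lists trimmed to AC220 lengths the unstained class turned slightly positive (0.03 and 0.05).

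The 5 bands whose smaller difference of the sets was most negative were 8q21.12 and 13q33.2, which are unstained, and 12q21.31, 10q21.1 and 8q23.3, which are of the darkest class. In 8q21.12 the covered share was 2.77% in DMSO 1 and 0.740% in AC220 1, and 19% in DMSO 2 and 8.03% in AC220 2. In 12q21.31 it was 52.7% lower with AC220 in both sets. In 13q33.2 it was 69.7% and 48.3% lower, in 10q21.1 61.0% and 46.2% lower, and in 8q23.3 46.1% and 43.7% lower. In DMSO 1 the shares were 2.12% in 12q21.31, 2.69% in 13q33.2, 2.90% in 8q23.3 and 4.13% in 10q21.1. All but the last lay near the 2% minimum set for DMSO alone, which can favour lower values with AC220. The 5 bands highest with AC220 by the same rule were all unstained. They were 6p21.31 (16.5% higher in set 1 and 15% in set 2), 11q13.1 (15.8% and 14.7%), 9q34.11 (14.6% and 15.1%), 16q22.1 (15.9% and 13.8%) and 1p36.11 (19% and 13.7%). All 10 bands kept their direction in both sets with each DMSO list trimmed to its AC220 length and with all lists trimmed to equal length. The first trimming removes DMSO coverage alone, so the 5 higher bands could not change direction under it. In set 1 both settings are the same. The 5 lower bands had been chosen for large differences in these same data, so their kept direction is weak evidence.

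Bands that hold genes of FLT3-driven leukaemia and myeloid differentiation were mostly lower with AC220, in many cases by less than the genome-wide log2 ratio of -0.27 in set 1 and -0.25 in set 2. Of 15 such bands, 11 were lower with AC220 in both sets, 2 were higher and 2 went in opposite directions. In 8q24.21, the band of the growth regulator MYC, the covered share was 11.7% in DMSO 1 and 7.22% in AC220 1, and 32.4% in DMSO 2 and 25% in AC220 2. In 9p21.3, the band of the cell cycle inhibitor CDKN2A, it was 1.72% and 1.25% in set 1 and 8.04% and 5.37% in set 2. In 2p14, the band of the leukaemia-associated homeobox gene MEIS1, it was 17.1% and 18.5% lower, and in 5q32, which holds the macrophage growth factor receptor gene CSF1R, 18.3% and 16.9% lower. The band of CEBPA, a factor of granulocyte commitment (19q13.11), was 19.1% and 2.46% lower. Other bands of myeloid regulators were 11p11.2 (SPI1, which encodes the myeloid transcription factor PU.1), at 4.17% and 1.91% lower, and 14q11.2 (CEBPE, a factor of granulocyte maturation), at 2.84% and 10.3% lower. In 5q31.3, the band of the monocyte receptor gene CD14, the shares were 7.55% and 7.94% in set 1 and 18.4% and 16.6% in set 2, in opposite directions. In 16p11.2, the band of the myeloid integrin gene ITGAM, AC220 was higher in both sets, at 1.19% against 1.14% and 3.69% against 3.30%. The bands of FLT3 itself (13q12.2) and of EZH2 (7q36.1), which encodes the catalytic subunit of PRC2, were 5.22% and 0.259%, and 12.4% and 8.89%, lower.

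The bands of the HOX clusters had no common direction. In 7p15.2, the HOXA band, the covered share was 5.69% in DMSO 1 and 6.91% in AC220 1, and 17.8% in DMSO 2 and 17.5% in AC220 2. In 12q13.13, the HOXC band, AC220 was slightly higher in both sets, at 20.6% against 20.2% and 35.5% against 34.5%. In 17q21.32, the HOXB band, it was 6.59% and 1.37% lower, and in 2q31.1, the HOXD band, 9.32% and 6.10% lower. With each DMSO list trimmed to its AC220 length, 2 of the 15 bands (8q24.21 and 9p21.3) were lower in both sets, 9 were higher and 4 went in opposite directions; with all lists at equal length, 8q24.21 alone was lower in both. A band holds many other genes, the bands stand in for the named genes after the data had been seen, and nothing in these values places the mark on a given gene.

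Windows of 5 kb were then compared. A window was called lower with AC220 when the smaller DMSO covered share exceeded the larger AC220 share by at least 25 percentage points, and higher in the reverse case. Of 607271 windows, 536 were lower and 104 higher. They formed 528 and 104 separate regions, so few adjoined each other. Windows lower with AC220 were most numerous in 12q24.21 (11 windows), 1q41 (9), 19q12 and 8q24.12 (8 each), and windows higher with AC220 in 10q22.1 (6). Unstained bands held 42.2% of the lower windows and 74.0% of the higher ones, against 42.4% of all windows. The darkest class held 14.6% of the lower windows against 16.4% of all windows. A window could be called lower only where both DMSO libraries covered at least 25% of it, and higher only where both AC220 libraries did. The darkest class was less covered with DMSO, at 2.98% in DMSO 1 and 12% in DMSO 2, against 9.99% and 23.1% in unstained bands. It was also less covered with AC220, at 2.05% in AC220 1 and 7.93% in AC220 2, against 8.61% and 20.6% in unstained bands. Shares of all windows therefore do not show in which class lower or higher windows were concentrated.

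The longest regions lower with AC220 spanned 10 kb each. There were 8 of that length, and the 5 with the largest mean separation are given. The first lay in 7p14.1 (chromosome 7, 42645001 to 42655000), covered over 50.4% in DMSO 1 and 58.3% in DMSO 2, and over 0% in AC220 1 and 9.71% in AC220 2. In 12q24.21 (chromosome 12, 115275001 to 115285000) the shares were 36.7% and 57.0% with DMSO and 0% and 0.980% with AC220. In 1q32.2 (chromosome 1, 208780001 to 208790000) they were 78.4% and 81.5%, and 14.7% and 41.8%. In 7q31.1 (chromosome 7, 108240001 to 108250000) they were 90.2% and 100%, and 26.6% and 55.1%. In 5p15.32 (chromosome 5, 5750001 to 5760000) they were 92.5% and 100%, and 22.7% and 59.4%. All 104 regions higher with AC220 spanned 5 kb each, and the 5 with the largest separation are given. In 11q23.2 (chromosome 11, 112600001 to 112605000) the shares were 26.7% and 37.3% with DMSO and 100% and 91.7% with AC220. In 14q23.1 (chromosome 14, 58515001 to 58520000) they were 0% and 13%, and 61.8% and 69.0%. In 10q11.21 (chromosome 10, 43730001 to 43735000) they were 36.2% and 26.0%, and 83.8% and 100%. In 7p22.3 (chromosome 7, 1430001 to 1435000) they were 17.8% and 32.5%, and 100% and 79.9%. In 5q31.2 (chromosome 5, 137220001 to 137225000) no base was covered with DMSO, and 48.8% and 45.5% were covered with AC220.

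The same rule was applied to the other splits of the 4 libraries as a measure of its error. DMSO 1 and AC220 2 against DMSO 2 and AC220 1 gave 160 and 93 windows, 253 in all against 640 for the treatments, and set 1 against set 2 gave 1 and 66373. The 3 splits are too few to give a test. In simulated lists of 10000 windows, where each library's peak widths were drawn separately, the rule called 430 windows beyond those planted. Those lists differ from the real ones, where 640 of 607271 windows were called, so they do not give the error of the real calls. With 253 windows called in the crossed split, single called windows are not secure. With all lists trimmed to equal covered length the treatments gave 1739 lower and 1820 higher windows, so the excess of lower windows was lost, and the crossed split gave 1510 and 905. With each DMSO list trimmed to its AC220 length the excess turned round, to 264 lower and 994 higher windows, and the crossed split gave 573 and 74. Between treatments, that trimming can only remove lower windows and add higher ones. None of the 10 named regions remained separated by 25 points when peaks with a -log10 q of at least 2 alone were kept, and 2 of the 10 did at equal length.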

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

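Peaks on unplaced and unlocalised contigs lay outside the comparisons and were listed in every library: 83 in DMSO 1, 152 in DMSO 2, 94 in AC220 1 and 170 in AC220 2. They were singled out because the report's comparisons do not use these sequences. The contig GL000192.1 held the most, with 45, 52, 53 and 72 peaks in that order, covering 87.8 kb, 252 kb, 76.9 kb and 227 kb. No input list was used here, so no background level can be set beside these values, and no explanation of them was tested.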

How the results depend on the processing

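In the alternatives run, covered length, median width and the share in broad peaks stayed lower with AC220 except when a library was left out, and no exact permutation or sign-flip p can pass a threshold with 2 libraries per treatment. Log2 ratios without 1 library ran from -0.95 to 0.42 for covered length (above 0 without DMSO 2 or AC220 1), -0.087 to 0.33 for peak number (below 0 without AC220 2), -0.87 to 0.065 for median width (above 0 without DMSO 2) and -1.15 to 0.43 for the share in broad peaks (above 0 without DMSO 2 or AC220 1); each removal leaves the sets unbalanced. Peak number, at 0.12 on all peaks, turned to -0.17 at a -log10 q of at least 2 and -0.10 for peaks of at least 1 kb. The mean Jaccard index within treatments, 0.361, became 0.180, 0.336 and, at equal length, 0.418. The mean share of peaks shared within sets was 53.7%, and 70.5% at 1 bp of overlap.

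Lower windows numbered 536 and became 959 for peaks of at least 1 kb, 1739 at equal length, 1278 with peaks joined, 27 at a separation of 50 points, 22 in windows of 10 kb, 6323 in windows of 2 kb and 624 to 43902 without 1 library (43902 without DMSO 1, 21828 without AC220 2). Higher windows numbered 104 and became 184, 1820, 486, 1, 4, 1621 and 173 to 10513 in the same order (10513 without AC220 1, 8546 without DMSO 2, 192 without AC220 2, 173 without DMSO 1), and 55 at a -log10 q of at least 2. With each DMSO list trimmed to its AC220 length, a setting added after the data had been seen, 264 were lower and 994 higher. Of the 10 named regions, 10 stayed separated by 25 points for peaks of at least 1 kb, 6 with peaks joined, 2 at equal length and 0 at a -log10 q of at least 2. Chromosomes lower in both sets numbered 22, and 5 with each DMSO list trimmed to its AC220 length, as also at equal length. The difference between darkest and unstained bands was -0.38 on average, and -0.22 with that trimming. Read depth is unknown, so what it limits could not be set out. Other causes than the settings' construction were not tested. The settings on chromosomes and stain were chosen after the data had been seen.

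With the replicate number as a replicate block, covered length gave -0.26 (exact sign-flip p = 0.5, the smallest possible), peak number 0.12, median width -0.40 and the share in broad peaks -0.36; lower windows became 4398 and higher ones 640, with 2093 in opposite directions. Libraries of one number deviated together from their treatment means across windows (correlation 0.70). The DMSO minus AC220 differences of the sets were hardly correlated across windows (0.087). The 2 pairs, with no label of a shared batch, do not make the numbers a paired design, and the Jaccard index takes no block. Not run for want of an annotation of this build: promoters, gene lists, named genes and their alternatives.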

Other observations

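AC220 peaks split DMSO peaks more often than the reverse. Of DMSO 1 peaks, 11.1% were overlapped by at least 2 AC220 1 peaks, and 5.93% of AC220 1 peaks by at least 2 DMSO 1 peaks. In set 2 the shares were 19.4% and 4.64%. Peaks with no overlap in the other treatment's library of the same number made up 40.1% of DMSO 1 and 32.1% of AC220 1 peaks. In set 2 they made up 27.2% of DMSO 2 and 18.9% of AC220 2 peaks. They do not all lack a counterpart in the other treatment. Of DMSO 1 peaks, 84.1% had at least 50% of their length inside AC220 2 peaks, and of AC220 1 peaks 91.2% inside DMSO 2 peaks. The DMSO list covered more length in each set, which bears on these shares. Where 5 kb windows were at least 50% covered, 23269 were so in all 4 libraries, which is 61.0% of such windows in DMSO 1, 77.8% in AC220 1, 20.3% in DMSO 2 and 24.6% in AC220 2.

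The peaks of highest deposited -log10 q were present under both treatments: all 20 taken as the leading 5 of each list had a peak in all 4 libraries. The 20 are not distinct places, because a place that led several lists was counted for each of them. One in 20q13.13 was among the leading 5 of both libraries of set 1 (chromosome 20, 47128059 to 47133931 in DMSO 1 and 47130273 to 47133958 in AC220 1). One in 1q22 led DMSO 2 (chromosome 1, 155049922 to 155056601, -log10 q of 31) and was among the leading 5 of AC220 2. A peak of 0.738 kb in 11p11.12 (chromosome 11, 51592474 to 51593211), close to the centromere, led DMSO 1 with a -log10 q of 17 and was among the leading 5 of both AC220 lists.

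The test of background level in set 1 and the choice of all the explanations below came after the patterns had been seen. The lower covered length with AC220 in both sets was set against 3 technical explanations. If a lower effective depth caused it in set 1, the implied background would be lower in AC220 1. This background was derived from the fold and p of the repeated shortest peaks under the peak caller's Poisson formula. Its lowest solution in AC220 1 was 1.17 times the highest solution in DMSO 1, which argues against that. No solution in either library of set 1 had a whole read count, so this rests on the assumed formula. If a higher fold needed for a call caused it in set 2, removing DMSO 2 peaks below the fold of the repeated shortest AC220 2 peaks (1.91) would close the gap. After that, 573 Mb were left, 1.155 times the AC220 2 length, though this leaves peak edges untouched. Depth in set 2 was not tested. The solutions for the implied background overlapped there, at 6.0 to 8.06 in DMSO 2 and 5.81 to 7.84 in AC220 2 per shortest peak width. Those with a whole read count were 6.0 in DMSO 2 and 5.81 in AC220 2 per shortest peak width, but 21.6 and 26.1 per kb. The direction of the implied background thus depended on the measure. If peak edges moved by a shorter fragment extension caused it, trimming every DMSO peak by the difference in shortest peak width would close the gap. That trimming, by 31 bp in set 1 and 55 bp in set 2, removed 8.18% and 6.87% of the gap. It left out edges inside peaks that were split and any effect of extension on calling, so these shares are not upper limits. A lower signal-to-background ratio of the AC220 immunoprecipitations and an effect of the treatment on the mark both stay open as hypotheses; the spike-in scale that bears on them was not used here.

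The larger relative difference in dark bands was set against 2 technical explanations. Fewer weak peaks called with AC220 across the genome would remove it when each DMSO list is trimmed to the length of its AC220 list. The difference between darkest and unstained bands went from -0.38 to -0.22, so part of it went with list length. The remainder does not decide, because the darkest bands also differed most between libraries of the same treatment. Their covered share in DMSO 2 was 4.03 times that in DMSO 1, against 2.31 times in unstained bands. For AC220 these ratios were 3.87 and 2.39. Trimming drops whole peaks and not their edges, so weaker calling at edges stays open. A lower starting coverage of dark bands would remove it among bands of like DMSO coverage, but within the 4 of 5 equal classes of DMSO share that held at least 3 bands of each kind it was -0.40 on average over the sets. GC bias between libraries was not tested, since no genome sequence was used here, and it stays open beside the treatment, which may act on gene-poor chromatin as an untested hypothesis.

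The excess of lower over higher windows may come from the unequal length of the lists: with all lists trimmed to equal length the ratio of lower to higher windows was 0.956. With each DMSO list trimmed to its AC220 length the excess turned round, to 264 lower and 994 higher. That trimming can only remove lower windows and add higher ones. The direction of the windows thus depended on how the lists were scaled. No biological explanation of the excess was tested.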
